A study of Mus musculus with 42 samples.

How the data were processed

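The deposited matrix held the authors' counts for 49585 genes in 42 columns. Per the submitters' processing notes, reads were aligned with STAR 2.6.0b to GRCm38 and DESeq2 was used; the version of DESeq2, the counter and the annotation release were not given in the sources used here. Sex, irradiation dose and harvest time of day were not in the labels. Per the labels the mice were of mixed BALB/c and C57BL/6 background and organs were taken 4 h after irradiation or without it. Columns were matched to samples by animal number, genotype and tissue in the column name. For 8 basal thymus columns the name carried no tissue, and they were matched as the only columns left for those animals. Gene symbols and positions came from the GENCODE M21 annotation, which matched 49326 gene identifiers and missed 259.

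Analysis ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Groups were fitted together by setting: irradiated thymus (16 libraries, 22206 genes tested, biological coefficient of variation 0.153), basal thymus (8, 22173, 0.119), intestine (6, 20011, 0.216), liver (6, 15755, 0.237), pancreas (6, 14604, 0.184), the 4 basal tissues of AD and Null (23, 24431, 0.205) and all thymus (24, 23605, 0.145). Genes were filtered by filterByExpr, scaled by TMM and tested by robust quasi-likelihood F tests in edgeR, and a call meant a Benjamini-Hochberg adjusted p under 0.05. Log2 CPM used a prior count of 2. Gene lists, 53 in number and written before the fits, were tested with camera at the preset correlation of 0.01 and again with an estimated correlation, and with fry.

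Genes were named by a fixed rule: Trp53 and a fixed set of p53 targets and regulators in every comparison, then up to 10 called genes in each direction by size of change (5 for an interaction) with a mean of at least 1 log2 CPM, and up to 4 members for a list. Any other gene is said in the text to have been chosen after its value was seen. Some genes that met the rule are not reported here.

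The 10 most abundant genes took 50.2 to 53.5% of counts in pancreas, 19.3 to 23% in liver, 11.8 to 15.3% in thymus and 8.8 to 13% in intestine. Among 49 pairs of libraries within groups the chi-square per degree of freedom was 4.85 to 327, so no library was a copy of another of its group, and pairs across groups were not compared. For 33 pairs of tissues from the same mouse, the correlation of residuals over 10384 genes was above 0 in all pairs, with a median of 0.145 (0.004 to 0.534) and 22 pairs above 0.1, and the pairing itself was taken from the animal numbers in the labels. In simulated data with known changes, edgeR recovered 36.9% of changes of 1.5-fold, 61.2% of 2-fold and 93.8% of 4-fold in irradiated AD against Null thymus, and 1.52%, 39.4% and 80% in liver. False calls among all calls in these data were 12 of 137 and 12 of 91, and they were 19 of 145 for basal thymus AD against Null and 24 of 160 for AD against Het, above the nominal 5%.

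Alternatives fixed before the values were seen were RLE scaling, no filter, an Xist covariate for sex, DESeq2, only the 2 groups compared, a block for mouse in the tissue interaction, an estimated correlation for the lists and leaving out each library. An Adipoq covariate for basal thymus was added after the data were seen. RLE in place of TMM moved the median log2 fold change by at most 0.007 over 16 comparisons.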

Results

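RNA sequencing counts were analysed for 42 libraries from thymus, intestine, liver and pancreas of mice aged 4 weeks with 4 Trp53 genotypes. Null mice had no wild-type Trp53, Het mice had 1 wild-type allele, and AD and RP mice had 1 copy of the mutant allele of that name over a null allele. Irradiated thymus, taken 4 h after exposure, came from 4 mice each of Null, Het, AD and RP. Basal thymus came from 2 Null, 3 Het and 3 AD mice, and basal intestine, liver and pancreas each came from 3 AD and 3 Null mice. Libraries held 26.4e6 to 33.3e6 counts in thymus, 24.3e6 to 34.8e6 in intestine, 26.0e6 to 32.5e6 in liver and 19.9e6 to 24.8e6 in pancreas. A library is named by genotype and animal number, as in AD-727. Values after ± are standard errors of a log2 fold change unless SD is written, and n is the number of mice. The p-values describe variation among these few mice of each group, and they do not cover a repeat of the whole experiment on other days or in another colony.

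The targeted gene was read first. Trp53 encodes the p53 transcription factor and lies on chromosome 11 from 69580359 to 69591873 on GRCm38. In irradiated thymus Trp53 stood at 19.9 CPM (counts scaled to library size) in Null (SD 1.02, n = 4), 31.4 in Het (SD 1.15, n = 4), 35.4 in AD (SD 2.41, n = 4) and 33.7 in RP (SD 1.55, n = 4). In basal thymus it stood at 21.2 CPM in Null (SD 1.02, n = 2), 37.2 in Het (SD 2.64, n = 3) and 33.7 in AD (SD 3.75, n = 3). In basal intestine the means were 15.1 CPM in AD (SD 0.525, n = 3) and 9.88 in Null (SD 0.319, n = 3), in liver they were 4.57 and 4.01, and in pancreas they were 3.47 (SD 0.749, n = 3) and 4.32 (SD 0.429, n = 3). Trp53 transcript was present in every Null group. Its difference between AD and Null was not called in intestine, liver or pancreas, so genotype was read from the labels.

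Irradiated thymus with 1 wild-type allele was set against irradiated Null thymus to find transcripts that depended on p53. The cell cycle inhibitor Cdkn1a rose from 3.59 CPM (SD 0.414, n = 4) to 42.2 CPM (SD 2.63, n = 4), a log2 fold change of 3.55 ± 0.12. The death genes Bbc3 (4.39 ± 0.18) and Bax (12.7 to 77.4 CPM) rose, as did Ccng1 (2.81 ± 0.09), the Akt inhibitor Phlda3 (2.98 ± 0.17) and the p53 ligase Mdm2 (0.73 ± 0.05). The largest rises by the naming rule also held the secreted factor Gdf15 (5.43 ± 0.39), the T cell costimulator Tnfsf4 (5.50 ± 0.22), Dglucy (4.28 ± 0.10), Ccn1 (3.96 ± 0.27), Atf3 (3.95 ± 0.21), the kinase Plk2 (3.83 ± 0.12), Thbs1 (3.76 ± 0.37), Eda2r (3.68 ± 0.22) and Capn11 (4.69 ± 1.52). Among the genes that fell were the amino acid transaminase Bcat1 (-2.49 ± 0.32), the nucleotide enzyme Dctd (-2.17 ± 0.24), Srm of polyamine synthesis (-1.58 ± 0.28), and the nucleolar genes Dkc1 (-1.33 ± 0.19) and Gnl3 (-1.31 ± 0.15). The killer cell gene Gzma fell by -3.28 ± 0.82, with a Null mean of 190 CPM and an SD of 281 (n = 4). By edgeR 4257 of 22206 genes were called, 2173 higher and 2084 lower, and the adjusted p was 1.54e-13 for Cdkn1a, 2.33e-11 for Bbc3, 0.0141 for Gzma and 0.0485 for Capn11. With only the 2 groups in the fit 2208 genes were called and Gzma and Chst3 (-1.47 ± 0.36 in the full fit) were not, and Capn11 lost its call without any of the libraries but Het-594.

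Gene lists gave the same contrast by function. Of 26 measured p53 targets of cell cycle arrest and repair, 20 rose and 0 fell (20 and 1 adjusted over the list alone), among them the repair polymerase Polk (2.42 ± 0.07), and the list median was 2.03. Of 20 p53 apoptosis targets 14 rose and 1 fell (15 and 1 adjusted over the list alone), including Apaf1 (1.98 ± 0.05), Aen (2.76) and Pmaip1 (2.64). Of 17 p53 metabolism targets 12 rose and 0 fell (12 and 0 adjusted over the list alone), including the thiamine carrier Slc19a2 (2.02), the lipid phosphatase Lpin1 (1.41) and the lysosomal Fuca1 (1.31). Immediate early genes rose in 14 of 20 with 1 lower (14 and 1 adjusted over the list alone; Dusp1 1.32), and NF-kB targets in 11 of 23 with 0 lower (14 and 0 adjusted over the list alone; Ccl2 3.67 ± 0.25, Ccl3 3.62, Il1b 2.30). By camera with edgeR counts the adjusted p with an estimated correlation was 1.69e-09 for cycle and repair, 3.28e-06 for apoptosis, 8.52e-05 for metabolism, 0.0208 for immediate early genes and 0.0467 for NF-kB targets. Cholesterol synthesis genes fell in 13 of 25 with 0 higher (14 and 0 adjusted over the list alone; Cyp51 -0.91 ± 0.07, Sqle -0.94), and the list had edgeR adjusted p = 1.19e-09 at the preset correlation and adjusted p = 0.126 with an estimated correlation. Oxidative phosphorylation genes fell in 24 of 59 with 0 higher (35 and 0 adjusted over the list alone; Cycs -0.58), with adjusted p = 2.73e-08 on edgeR values and adjusted p = 0.802 with an estimated correlation. Replication genes repressed through DREAM fell in 19 of 50 with 0 higher (30 and 0 adjusted over the list alone; Chek1 -0.73, Mcm6 -0.82, Ung -1.29), with adjusted p = 7.67e-11 on edgeR values and adjusted p = 0.62 with an estimated correlation. Thymic epithelium markers, which belong to another cell type than the thymocytes, rose in 9 of 16 (10 adjusted over the list alone; Krt8 0.91, Prss16 0.59), with adjusted p = 2.92e-07 on edgeR values and adjusted p = 0.177 with an estimated correlation.

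**Figure D1:**
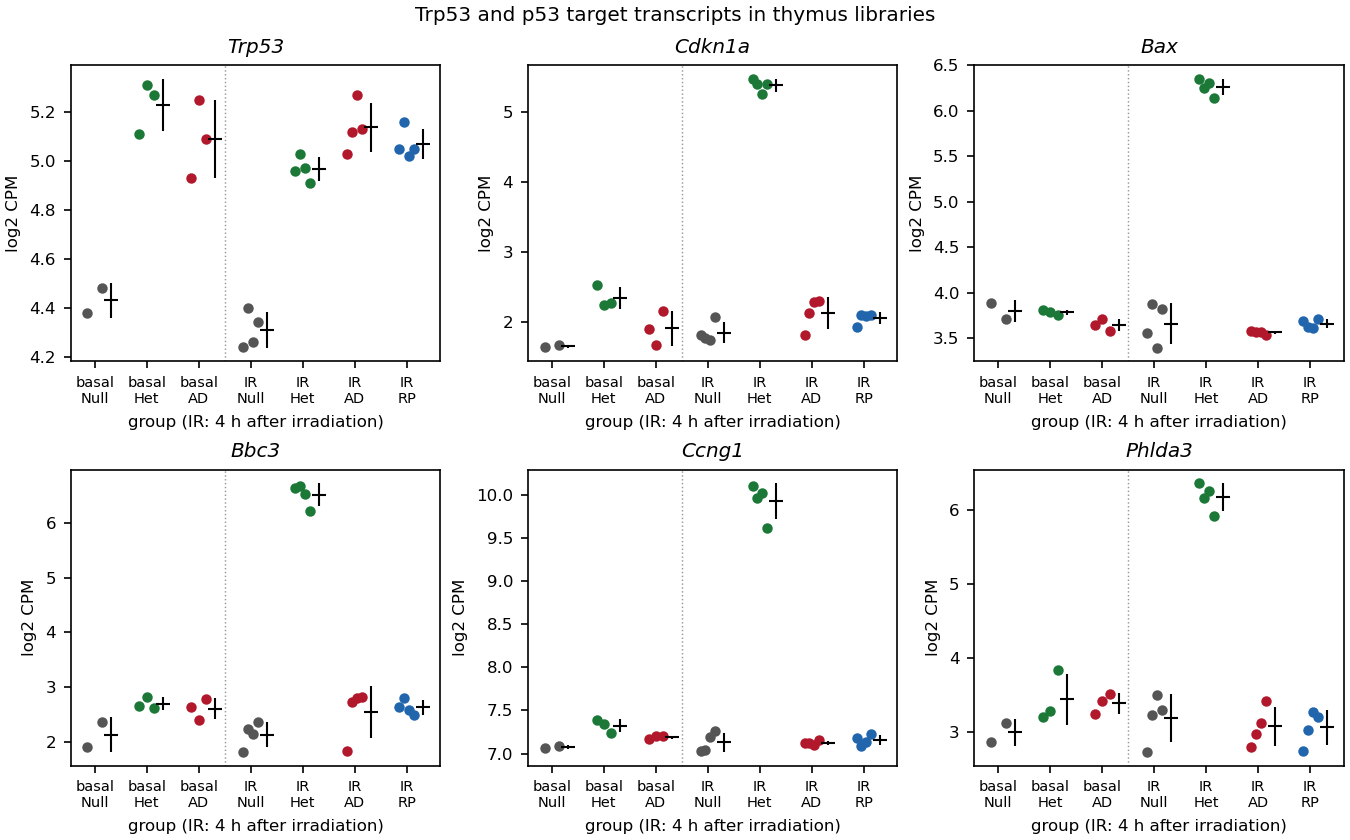
Log2 CPM of Trp53 and p53 targets in each thymus library of the 7 thymus groups, with dashes for the group mean and bars for the SD. Irradiated Het libraries stood apart for the targets, with Cdkn1a at 42.2 CPM against 3.59 in Null, 4.40 in AD and 4.13 in RP.

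Irradiated AD thymus was set against irradiated Null thymus to ask whether the AD protein induced p53 targets. No p53 target of the fixed list was called: Cdkn1a stood at 4.40 CPM (SD 0.666, n = 4) against 3.59 (SD 0.414, n = 4), a log2 difference of 0.29 ± 0.12, with Bbc3 at 0.46 ± 0.18, Bax at -0.11, Mdm2 at 0.03, Ccng1 at -0.01 and Phlda3 at -0.12. The Bbc3 mean held 1 low library, AD-630 at 1.85 log2 CPM. The other AD libraries stood at 2.74 to 2.84 and the Null libraries at 1.83 to 2.37. The transcripts that did rise lay beside Trp53 on chromosome 11: Trp53 itself (0.83 ± 0.07), the germ cell RNA-binding gene Ybx2 (3.63 ± 0.35, from 1.08 to 13.5 CPM), and, chosen after their values were seen, the inflammasome gene Nlrp1a (3.57 ± 0.38), the related pseudogene Nlrp1c-ps (7.36 ± 0.46) and the receptor gene Gucy2e (2.31 ± 0.38). The interferon-induced Xaf1 of the same region fell (-0.95 ± 0.15). By edgeR 6 genes were called, 5 higher and 1 lower, with adjusted p = 2.48e-06 for Trp53, 0.000111 for Ybx2, 0.0191 for Xaf1 and 0.542 for Cdkn1a. Of the 26, 20 and 17 measured p53 targets of cycle and repair, apoptosis and metabolism 0 were called, and the list medians were -0.01, -0.11 and -0.01 with camera adjusted p of 0.989, 0.0536 and 0.922 on edgeR values; the apoptosis list passed the threshold, at -0.12, under RLE scaling and without the filter. Targets of the PPAR lipid receptors had a median of 0.05 with 0 of 75 called (adjusted p = 0.0875, edgeR values) and fatty acid oxidation genes 0.02 (adjusted p = 0.233, edgeR values). Hepatocyte markers, of another cell type, had a median of 1.91 with adjusted p = 0.0248 on edgeR values and adjusted p = 0.952 with an estimated correlation, and the call was also lost without Null-593 or Null-857. The hepatocyte median was -0.19 without AD-727, where Alb reached 7.47 log2 CPM. B and plasma cell markers had a median of -0.41, with adjusted p = 9.99e-05 on edgeR values and adjusted p = 0.925 with an estimated correlation. Without AD-630 the count was 27 and without Null-593 it was 22, and Xaf1 and Gucy2e lost their calls without AD-726, AD-727, Null-604 or Null-856, Xaf1 also without Null-857.

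Irradiated RP thymus differed in nearly the same genes from the same 4 Null libraries. Trp53 rose by 0.76 ± 0.07 and Ybx2 by 3.40 ± 0.35 (n = 4 and 4), and, chosen after their values were seen, Nlrp1a (3.99 ± 0.37), Nlrp1c-ps (7.09 ± 0.47) and Gucy2e (2.45 ± 0.37) rose. Xaf1 (-0.86 ± 0.14) and the gene Gm6685 (-0.97 ± 0.16, chosen after its value was seen) fell. Cdkn1a stood at 4.13 CPM (SD 0.254, n = 4), 0.20 ± 0.12 above Null, with Bbc3 at 0.49 ± 0.18, Bax at -0.01 and Mdm2 at 0.06. By edgeR 7 genes were called, 5 higher and 2 lower, with adjusted p = 1.11e-05 for Trp53, 0.000241 for Ybx2, 0.047 for Xaf1, 0.998 for Cdkn1a and 0.851 for Bbc3. The 3 p53 target lists had medians of 0.03, -0.01 and -0.01 with 0 genes called and camera adjusted p of 0.579, 0.571 and 0.837 on edgeR values. Cholesterol synthesis genes had a median of 0.14, with adjusted p = 3.07e-06 on edgeR values and adjusted p = 0.837 with an estimated correlation. B and plasma cell markers had a median of -0.38 with 0 and 6 called higher and lower adjusted over the list alone, adjusted p = 6.86e-08 on edgeR values and adjusted p = 0.837 with an estimated correlation. Without Null-604 or without RP-656 the count was 4, Xaf1 lost its call whichever library was left out, and Gucy2e lost it without Null-604, Null-856, RP-649 or RP-656.

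**Figure D2:**
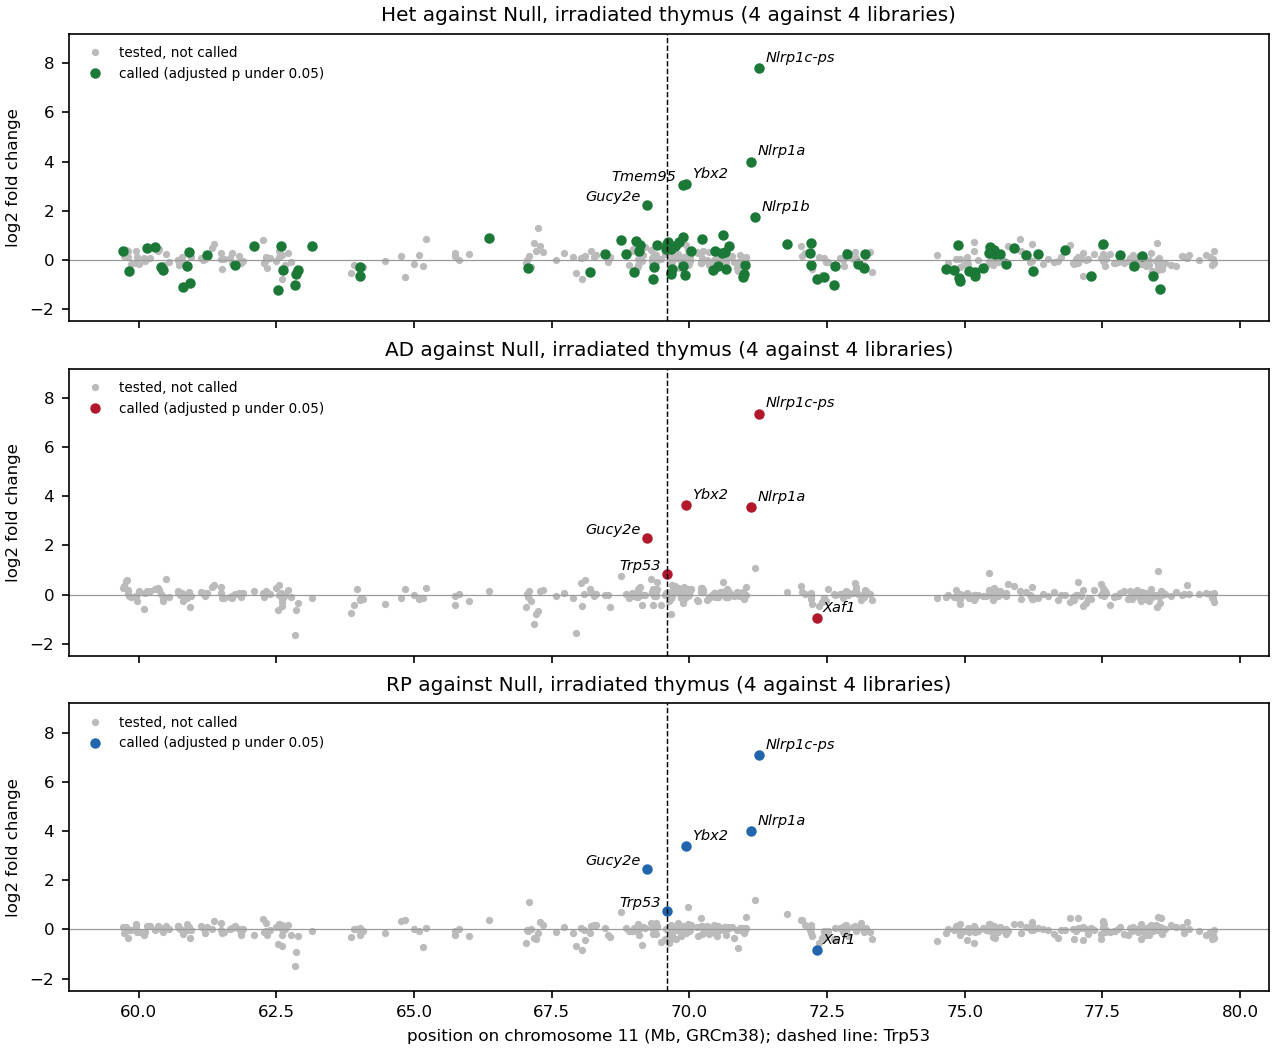
Log2 fold change against position on chromosome 11 for genes within 10 Mb of Trp53 (dashed line) in irradiated Het, AD and RP thymus against Null, with called genes coloured. Ybx2, at 3.63 in AD and 3.40 in RP, and its neighbours stood out in the same places in all 3 panels.

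AD and RP thymus were compared directly after irradiation. Cdkn1a (0.09 ± 0.12), Bbc3 (-0.02), Bax (-0.10 ± 0.09) and Trp53 (0.07 ± 0.07) were within about 1 standard error of equality (n = 4 and 4). Among PPAR targets the fatty acid carrier enzyme Cpt1a, chosen after its value was seen, stood 0.31 ± 0.09 higher in AD, with an edgeR adjusted p of 0.625. By edgeR 0 genes were called, with 1525 at unadjusted p under 0.05, and DESeq2 called 14. The PPAR list median was 0.12, with adjusted p = 0.0462 on edgeR values and adjusted p = 0.955 with an estimated correlation, and fatty acid oxidation stood at 0.11, with adjusted p = 0.0423 on edgeR values and adjusted p = 0.955 with an estimated correlation. Cholesterol synthesis genes stood at -0.19 with 0 higher and 3 lower adjusted over the list alone (Cyp51 -0.39 ± 0.07), with adjusted p = 8.28e-08 on edgeR values and adjusted p = 0.955 with an estimated correlation. With only these 2 groups in the fit 47 genes were called, 22 higher and 25 lower, and without AD-630 the full fit called 4. Without AD-727 the PPAR median was -0.02 and the fatty acid oxidation median 0.00, neither past the threshold, and both lists also lost it without AD-726, RP-653 or RP-654, PPAR also without RP-649.

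AD thymus was compared with Het thymus after irradiation, as mutant against wild-type protein at the same allele number. p53 targets were lower in AD: Cdkn1a by -3.26 ± 0.11, Bbc3 by -3.93 ± 0.18, Bax by -2.71 ± 0.09, Ccng1 by -2.82 ± 0.09, Phlda3 by -3.10 and Mdm2 by -0.70 (n = 4 and 4). Gdf15 (-5.05), Tnfsf4 (-4.92), Eda2r (-4.34), Dglucy (-4.30), Atf3 (-4.22), Plk2 (-4.07) and the monocyte chemokines Ccl2 (-4.05) and Ccl7 (-3.96) were lower as well. Dctd (1.83), Bcat1 (1.81), Tubb3 (1.48) and the repair glycosylase Ung (1.14) were higher, while Trp53 itself differed by 0.17 ± 0.07. By edgeR 3099 genes were called, 1263 higher and 1836 lower, with adjusted p = 4e-13 for Cdkn1a and 0.0877 for Trp53. Cycle and repair targets were lower in 21 of 26 with 0 higher (22 and 0 adjusted over the list alone), apoptosis targets in 14 of 20 with 1 higher (16 and 1 adjusted over the list alone) and metabolism targets in 11 of 17 with 0 higher (12 and 0 adjusted over the list alone), with edgeR adjusted p with an estimated correlation of 8.19e-10, 6.12e-07 and 5.53e-05. Macrophage markers, of another cell type, were lower in 6 of 16 (11 adjusted over the list alone) with a median of -0.48, adjusted p = 0.00112 on edgeR values and adjusted p = 0.693 with an estimated correlation. Without Het-631, the count was 4665.

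The responses of Het and AD to the same Null libraries were then correlated gene by gene. Over 21823 genes the correlation of the Het and AD log2 differences from Null was 0.348 and the covariance 0.0459. Since the same 4 Null libraries entered both differences, simulated groups of 4, 4 and 4 without any real difference had a covariance of 0.0347 (0.0334 to 0.0369) and a correlation of 0.487 (0.476 to 0.51) over 20 simulations. With the Null libraries split 2 and 2 so that no library was shared, the covariance had a median of 0.0152 (-0.00432 to 0.0214) and the correlation ran from -0.0241 to 0.143. In a fit of the 12 libraries 4 genes were called higher in both. The 20 simulations held no real difference and called 0 genes higher in either group, so they give no reference for this overlap. The 0.349 for independent lists leaves the shared Null libraries out of account. In the fit of 16 libraries the genes higher in both were Trp53, Ybx2, Nlrp1a, Nlrp1c-ps and Gucy2e. The observed covariance was above the simulated range but the observed correlation was below it, and most of the covariance was gone once no Null library was shared.

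Basal thymus of Het mice was compared with that of Null mice, before any irradiation. Trp53 rose by 0.81 ± 0.10, from 21.2 to 37.2 CPM (n = 3 and 2), and Ybx2 rose by 2.73 ± 0.26, with Nlrp1c-ps (4.93) and Nlrp1a (3.55), chosen after their values were seen, from the same region. The glycogen regulator Ppp1r3c (1.63 ± 0.27), the myelin gene Pmp22 (1.03), the myosin Myh10 (0.78 ± 0.11) and the collagen Col5a1 (0.77 ± 0.12) rose, while Trim16 (-1.50 ± 0.18), Fbxw10 (-1.40 ± 0.18) and the X-linked Chic1 (-1.75 ± 0.22) fell. Cdkn1a stood 0.71 ± 0.20 higher without a call. Of the genes named here Pmp22, Myh10, Trim16 and Fbxw10 also lay within 10 Mb of Trp53, as did 8 of the 15 calls. By edgeR 15 genes were called, 9 higher and 6 lower, with adjusted p = 0.00212 for Trp53, 0.00024 for Ybx2, 0.0319 for Ppp1r3c and 0.341 for Cdkn1a. Adipocyte markers, of another cell type, had a median of 1.40 with 7 higher and 0 lower of 19 adjusted over the list alone, adjusted p = 2.1e-22 on edgeR values and adjusted p = 0.59 with an estimated correlation. Fibroblast markers rose in 1 of 16 with 0 lower (13 and 0 adjusted over the list alone), with adjusted p = 2.32e-23 on edgeR values and adjusted p = 0.437 with an estimated correlation. PPAR targets had a median of 0.32 with 0 of 73 called, with adjusted p = 2.98e-12 on edgeR values and adjusted p = 0.689 with an estimated correlation. Without Het-697, the count was 234, without Null-923 it was 8, without Null-859 it was 23, and with an Adipoq covariate chosen after seeing the data it was 25, with PPAR targets at -0.33 and adipocyte markers at -0.44. Ppp1r3c, Pmp22 and Col5a1 lost their calls without Het-703, Het-855, Null-859 or Null-923, Chic1 and Myh10 without Null-923, Nlrp1a without either Null library, and Trp53, Trim16 and Fbxw10 only under the Adipoq covariate.

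Basal thymus of AD mice was compared with the same 2 Null libraries, so genes called in both comparisons can come from those libraries alone. Trp53 rose by 0.67 ± 0.10 (33.7 against 21.2 CPM, n = 3 and 2) and Ybx2 by 3.13 ± 0.26, with Nlrp1c-ps (5.38) and Nlrp1a (3.42), chosen after their values were seen. Myh10 (0.83) and the matrix gene Fn1 (0.66 ± 0.11) rose, Trim16 (-1.49), Fbxw10 (-1.27) and Chic1 (-1.70) fell, and Cdkn1a stood at 0.28 ± 0.20. Myh10, Trim16 and Fbxw10 lay within 10 Mb of Trp53, as did 7 of the 15 calls. By edgeR 15 genes were called, 8 higher and 7 lower, with adjusted p = 0.0156 for Trp53, 3.18e-05 for Ybx2, 0.0414 for Fn1 and 0.814 for Cdkn1a. PPAR targets had a median of 0.36 with 0 of 73 called and 8 higher and 0 lower adjusted over the list alone, adjusted p = 1.16e-20 on edgeR values and adjusted p = 0.348 with an estimated correlation. Fatty acid oxidation genes stood at 0.30 with 2 higher adjusted over the list alone, adjusted p = 9.19e-12 on edgeR values and adjusted p = 0.41 with an estimated correlation. Adipocyte markers, of another cell type, stood at 1.55 with 8 higher adjusted over the list alone, adjusted p = 6.39e-30 on edgeR values and adjusted p = 0.348 with an estimated correlation. Neutrophil markers stood at -0.83 with 4 lower adjusted over the list alone, adjusted p = 1.58e-09 on edgeR values and adjusted p = 0.348 with an estimated correlation. The count was 8 without Null-923, 7 without AD-701, 29 without AD-702 and 27 without AD-700, and it was 5 with an Adipoq covariate, with PPAR targets at -0.47 and adipocyte markers at -0.74. Trp53 lost its call without AD-701, Null-859 or Null-923, Nlrp1a without Null-859 or Null-923, Chic1, Myh10 and the neutrophil list (-0.21) without Null-923, Fbxw10 without AD-701 or Null-859, Fn1 without any library but Null-923, and all named genes under the Adipoq covariate.

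AD and Het basal thymus were compared to separate the mutant from the wild-type protein. PPAR targets stood 0.07 and fatty acid oxidation genes 0.07 higher in AD, and the interferon gene Ifit1 stood 0.40 ± 0.08 lower (n = 3 and 3). Skeletal muscle markers, of another cell type, stood at -2.67, with means of 5.16 log2 CPM in Het-697, 2.53 in Het-703 and 1.78 in Het-855 against 0.97 to 1.74 in AD. By edgeR 0 genes were called, with 775 at unadjusted p under 0.05, and DESeq2 called 12. On edgeR values the adjusted p for the PPAR, fatty acid oxidation, interferon and skeletal muscle lists was 0.00579, 0.0243, 1.13e-07 and 1.62e-11, and each had adjusted p = 0.967 with an estimated correlation. Without AD-702, 8 genes were called and the PPAR and fatty acid oxidation lists were not, and without Het-703 or AD-700 the count was 1. Without Het-697 the PPAR median was -0.09 and the fatty acid oxidation median -0.07.

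Basal intestine of AD mice differed from Null in 3 called genes. The inflammasome gene Nlrp1b rose from 1.54 CPM (SD 0.506, n = 3) to 15.8 CPM (SD 3, n = 3), by 3.33 ± 0.25, and, chosen after their values were seen, Nlrp1c-ps (8.88 ± 0.69) and the antibody segment Ighv3-4 (4.24 ± 0.32) rose. Nlrp1b and Nlrp1c-ps, 2 of the 3 calls, lay within 10 Mb of Trp53, in the region also called in thymus. Trp53 stood at 0.61 ± 0.10 and Cdkn1a at 0.37 without a call, and the lipid regulators Ppara (0.24), Ppard (0.21), Pparg (0.01) and Ppargc1a (0.37 ± 0.09) were not called. By edgeR the adjusted p was 0.00186 for Nlrp1b, 0.0088 for Nlrp1c-ps, 0.0019 for Ighv3-4, 0.199 for Trp53 and 0.454 for Ppargc1a. Clock genes had a median of 0.45 with 9 higher and 4 lower of 19 adjusted over the list alone (Dbp 2.07, Nr1d2 1.53 ± 0.25, Cry1 -0.82, Arntl -0.77), adjusted p = 2.71e-05 on edgeR values and adjusted p = 0.21 with an estimated correlation. Mitochondrially encoded genes stood at 0.47 with 7 of 11 higher adjusted over the list alone, adjusted p = 3.52e-10 on edgeR values and adjusted p = 0.114 with an estimated correlation. PPAR targets stood at 0.02 (adjusted p = 0.463, edgeR values) and fatty acid oxidation at -0.06 (adjusted p = 0.188, edgeR values). The acinar gene Prss2, of another tissue, stood at 12.83 log2 CPM in AD-702 and 12 in Null-923 against 5.5 to 9.88 in the others. Without AD-700, Null-859 or Null-1087, the count was 8, and without AD-702 or Null-923 it was 5, while Nlrp1c-ps lost its call without AD-701.

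Basal liver of AD mice differed from Null in circadian and sterol genes. The clock output factor Dbp rose from 0.444 CPM (SD 0.16, n = 3) to 13.7 CPM (SD 0.269, n = 3), by 4.95 ± 0.26, with Ciart (3.79 ± 0.42), the repressor Nr1d2 (2.05 ± 0.14) and Tef (1.83 ± 0.14), while the activators Npas2 (-1.77 ± 0.25) and Arntl (-1.03 ± 0.12) fell. The lipid receptor Ppard fell from 8.33 to 2.61 CPM (-1.67 ± 0.20) and the coactivator Ppargc1b rose (1.55 ± 0.25), with Ppara at 0.46 ± 0.27 and Pparg at 0.06 uncalled. The sterol genes Fdps (-1.05 ± 0.17) and Insig1 (-0.85 ± 0.12) and the fatty acid ligase Acsl3 (-0.82) fell. The gene Saa4 rose (1.19 ± 0.13), and Trp53 stood at 0.19 ± 0.22. By edgeR 42 genes were called, 24 higher and 18 lower, with adjusted p = 1.64e-05 for Dbp, 0.000184 for Nr1d2, 0.0104 for Ppard, 0.0342 for Fdps, 0.677 for Ppara and 0.857 for Trp53. Clock genes were called in 4 higher and 2 lower of 18 (11 and 4 adjusted over the list alone), with adjusted p = 1.92e-10 on edgeR values and adjusted p = 0.102 with an estimated correlation. Cholesterol synthesis genes fell in 3 of 25 (9 adjusted over the list alone; Lss -0.65 ± 0.10), with adjusted p = 2.58e-08 on edgeR values and adjusted p = 0.141 with an estimated correlation. PPAR targets had 0 higher and 2 lower of 73 (3 and 2 adjusted over the list alone) at a median of -0.02, adjusted p = 0.941 on edgeR values. Acinar markers, of another tissue, had a median of 3.88, with adjusted p = 0.0381 on edgeR values and adjusted p = 0.904 with an estimated correlation, and Prss2 stood at 6.33 log2 CPM in AD-702 against at most 1.74 elsewhere, and the median was -1.04 without AD-702, the call also ending without Null-859 or Null-923. The count was 4 without AD-700, 3 without AD-701, 9 without Null-923 and 87 without Null-859, and Dbp, Nr1d2 and Tef kept their calls throughout. Ciart and Saa4 lost theirs without AD-700 or AD-701, Ppard, Npas2 and Arntl also without Null-923, and Ppargc1b, Fdps, Lss, Insig1 and Acsl3 in 4 or 5 of 6 such fits.

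Basal pancreas of AD mice differed from Null in the clock repressors Nr1d1 and Nr1d2, of which Nr1d2 was also called in liver. Nr1d1 rose from 1.47 CPM (SD 0.481, n = 3) to 7.32 CPM (SD 2.36, n = 3), by 2.31 ± 0.28, and Nr1d2 rose by 1.52 ± 0.17. The amino acid enzymes Gpt (1.14 ± 0.15) and Arg2 (0.99 ± 0.15) and the membrane gene Lrrn1 (0.87 ± 0.14) rose, and the chromatin remodeller Hells fell (-1.55 ± 0.23). Trp53 (-0.31 ± 0.22), Cdkn1a (0.37), Ppara (0.37), Ppard (0.24), Pparg (0.28) and Ppargc1a (0.64 ± 0.23) were not called. By edgeR 8 genes were called, 7 higher and 1 lower, with adjusted p = 0.00408 for Nr1d1, 0.00136 for Nr1d2, 0.0065 for Gpt, 0.02 for Hells, 0.76 for Trp53 and 0.49 for Ppargc1a. Fatty acid oxidation genes had a median of 0.28 with 8 higher and 0 lower of 28 adjusted over the list alone (Cpt1a 0.91, Eci2 0.86), adjusted p = 6.79e-12 on edgeR values and adjusted p = 0.265 with an estimated correlation. PPAR targets stood at 0.28 with 10 higher and 1 lower of 57 adjusted over the list alone (Acadl 0.86 ± 0.18), adjusted p = 1.07e-08 on edgeR values and adjusted p = 0.265 with an estimated correlation. Replication genes of the DREAM list stood at -0.40 with 7 of 50 lower adjusted over the list alone (Mcm5 -0.90, Cdc6 -1.33), adjusted p = 6.04e-15 on edgeR values and adjusted p = 0.191 with an estimated correlation, and smooth muscle markers, of another cell type, stood at -0.91, adjusted p = 0.000771 on edgeR values and adjusted p = 0.569 with an estimated correlation (-0.26 without Null-859). The count was 26 without AD-702, 18 without Null-859, 4 without AD-700 or Null-923 and 5 without AD-701, and Arg2, Hells and Lrrn1 lost their calls without AD-700, AD-701 or Null-923, and Gpt without AD-700 or Null-923.

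**Figure D3:**
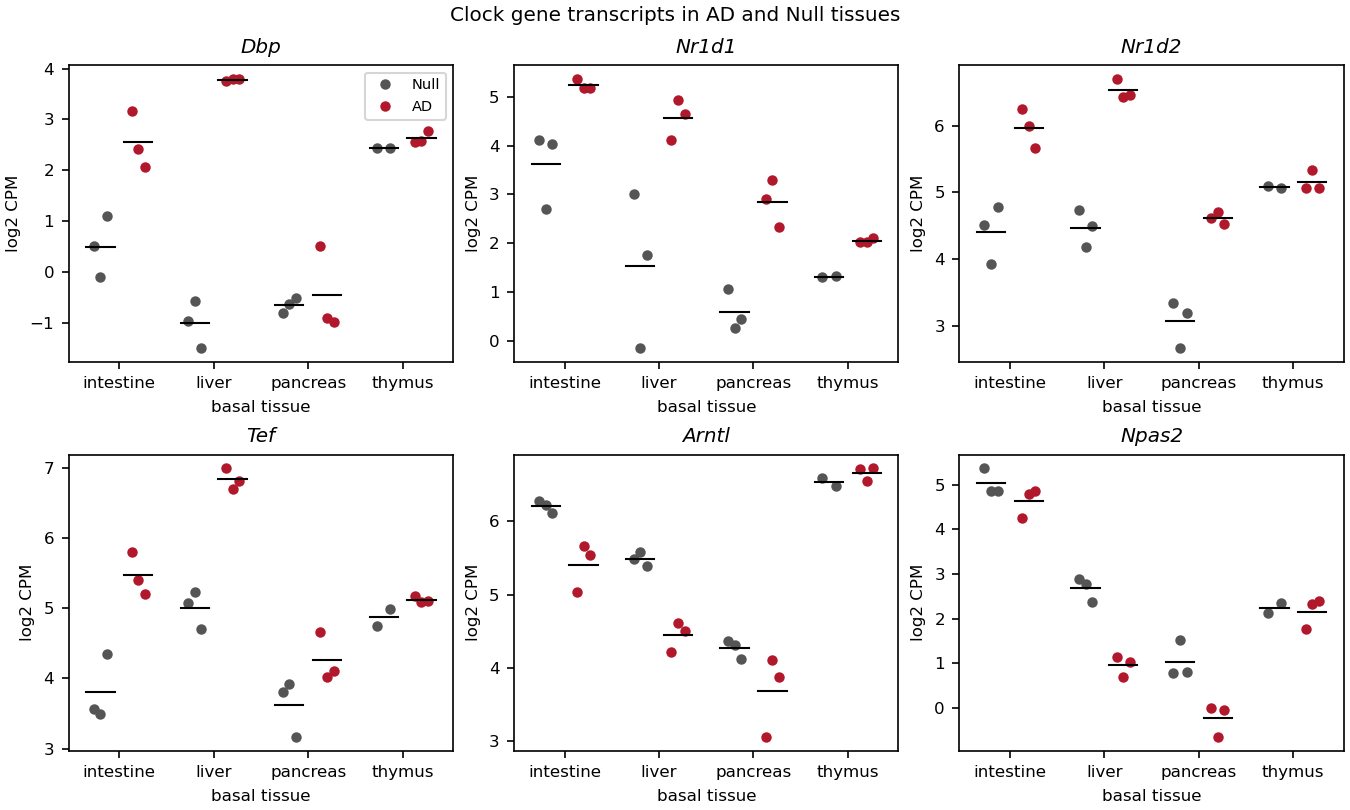
Log2 CPM of Dbp, Nr1d1, Nr1d2, Tef, Arntl and Npas2 in each basal library of intestine, liver, pancreas and thymus, AD beside Null, with lines at the group means. The Dbp difference of AD from Null was 4.95 in liver, where it was called, and 2.07 in intestine, 0.41 in pancreas and 0.20 in thymus, where it was not.

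The AD effect was compared across the 4 basal tissues, which came from the same mice except that Null-1087 had no thymus library. Nr1d2 was the only gene called in more than 1 of intestine, liver and pancreas, in liver and pancreas, and as the tissues came from the same mice no chance value is given. Genes whose AD difference changed with tissue included Nlrp1b, the phospholipase Pla2g4c, Dbp, Ppard, Ciart, the esterase Ces1d, Aifm2, Gpd1 and the ligase Acsl1. These genes were chosen after their values were seen. Ppp1r3c and Nr1d2 had smaller p than Gpd1 and Acsl1 in the same F test and were left out. Set against intestine, the AD difference of Ces1d, Aifm2, Gpd1 and Acsl1 stood higher mainly in thymus, by 2.552, 1.295, 1.504 and 1.584. Their liver values were 0.213, 0.348, -0.008 and -0.498, and their pancreas values were 0.649, -0.333, 0.662 and 0.197. Adipocyte markers had a median of 1.55 in AD against Null basal thymus, and whether fat tissue carried these genes was not tested. By edgeR the interaction called 42 genes, with adjusted p = 5.25e-05 for Nlrp1b, 6.18e-05 for Pla2g4c, 6.61e-05 for Dbp, 7.78e-05 for Ppard and 0.00673 for Acsl1. With a block for mouse it called 48. The count was 27 without intestine AD-702 or liver AD-701, 75 without pancreas AD-702, 17 without pancreas AD-700, 26 without pancreas AD-701, 8 without thymus Null-859, 7 without thymus Null-923, 24 without thymus AD-702 and 15 without thymus AD-701.

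Irradiated and basal thymus were compared within Null mice, which by the labels have no wild-type allele. Histone genes fell: Hist1h2ag (-1.42), Hist1h2ae (-1.28), Hist1h4i (-1.19) and Hist2h4 (-1.10, from 421 to 196 CPM), with the repair glycosylase Ung (-1.30 ± 0.19, n = 4 and 2) and Chic1 (-1.64 ± 0.30). The ubiquitin ligase gene Lonrf3 (1.06 ± 0.22), Zdhhc2 (0.94) and Pcdhgc4 (0.93) rose, while Cdkn1a stood at 0.21 ± 0.15 and Trp53 at -0.12. By edgeR 31 genes were called, 3 higher and 28 lower, with adjusted p = 0.00397 for Ung and 0.833 for Cdkn1a. Of 59 histone genes, a set chosen after its values were seen, 19 were lower at a median of -0.90, and no enrichment test was used for a set chosen in this way. Cycle and repair targets of p53 had a median of 0.04 (adjusted p = 0.91, edgeR values), and adipocyte markers, of another cell type, stood at 1.13, adjusted p = 1.52e-07 on edgeR values and adjusted p = 0.956 with an estimated correlation. The count was 0 without basal Null-923, 4 without basal Null-859, 17 without Null-593, 18 without Null-856 and 60 without Null-604, and only 3 with just the 2 groups in the fit. Every gene named as called here lost its call without basal Null-923 and with just the 2 groups, and all but Ung and Hist1h2ae without basal Null-859 as well. Irradiated and basal thymus came from different mice.

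The same comparison in Het mice gave the response with wild-type p53. Cdkn1a rose by 3.05 ± 0.13, Bbc3 by 3.83, Bax by 2.49, Ccng1 by 2.62, Phlda3 by 2.73 and Mdm2 by 0.70 (n = 4 and 3), with Gdf15 (5.12), Ccn1 (4.80), Tnfsf4 (4.74), Atf3 (4.25), Plk2 (4.15) and Ccl2 (3.83). Trp53 fell by -0.27 ± 0.08, Ung by -2.30 ± 0.18, Bcat1 by -2.31, the heat shock gene Hsph1 by -1.56 and the histone gene Hist1h4m by -2.99 ± 0.68. By edgeR 3972 genes were called, 2062 higher and 1910 lower, with adjusted p = 1.26e-14 for Cdkn1a and 0.0154 for Trp53, and Trp53 lost its call without Het-697 or Het-855. Cycle and repair targets rose in 24 of 26 with 0 lower (24 and 0 adjusted over the list alone; edgeR adjusted p = 4.56e-12 with an estimated correlation), apoptosis targets in 14 of 20 with 1 lower and metabolism targets in 11 of 17. Histone genes were lower in 54 of 59 at a median of -1.04. Skeletal muscle markers, of another cell type, fell in 11 of 15 (12 adjusted over the list alone), median -2.85, adjusted p = 0.681 with an estimated correlation (edgeR values), and -0.27 without basal Het-697. With just the 2 groups in the fit 2370 genes were called.

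In AD mice irradiated and basal thymus were compared in the same way. Histone genes fell in 50 of 59, Hist1h2an by -2.08 ± 0.36 and Hist1h4n by -2.02 ± 0.28, at a median of -1.09 (n = 4 and 3). Lonrf3 (0.94 ± 0.18), the cell cycle repressor E2f7 (0.82), Mybl1 (0.76 ± 0.12) and Pcdhgc4 (0.74) rose. Of the 26 measured genes on the fixed list of p53 cycle and repair targets, only the repair gene Ddb2 (0.41 ± 0.08) was called. Cdkn1a stood at 0.22 ± 0.13. By edgeR 129 genes were called, 39 higher and 90 lower, with adjusted p = 0.0126 for Lonrf3, 0.00127 for Mybl1, 0.0179 for Ddb2 and 0.506 for Cdkn1a. Cycle and repair targets had a median of -0.05 with 1 of 26 called (adjusted p = 0.509, edgeR values). Of the 28 genes lower in Null after irradiation 25 were also lower in AD (0.107 for independent genes) and 25 in Het (2.27 for independent genes). This overlap did not set AD apart from Het. Of the 28 genes 19 were histone genes, so the values for independent genes are no reference for chance. The count was 67 without AD-630, 70 without basal AD-701, 74 without basal AD-702, 77 without AD-726, 79 without AD-633 and 83 without basal AD-700, and 361 with just the 2 groups in the fit. Ddb2 lost its call without AD-630, basal AD-701 or basal AD-702, Lonrf3 without AD-726, basal AD-700 or basal AD-702, Pcdhgc4 in 4 and E2f7 in 6 of the 7 such fits.

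**Figure D4:**
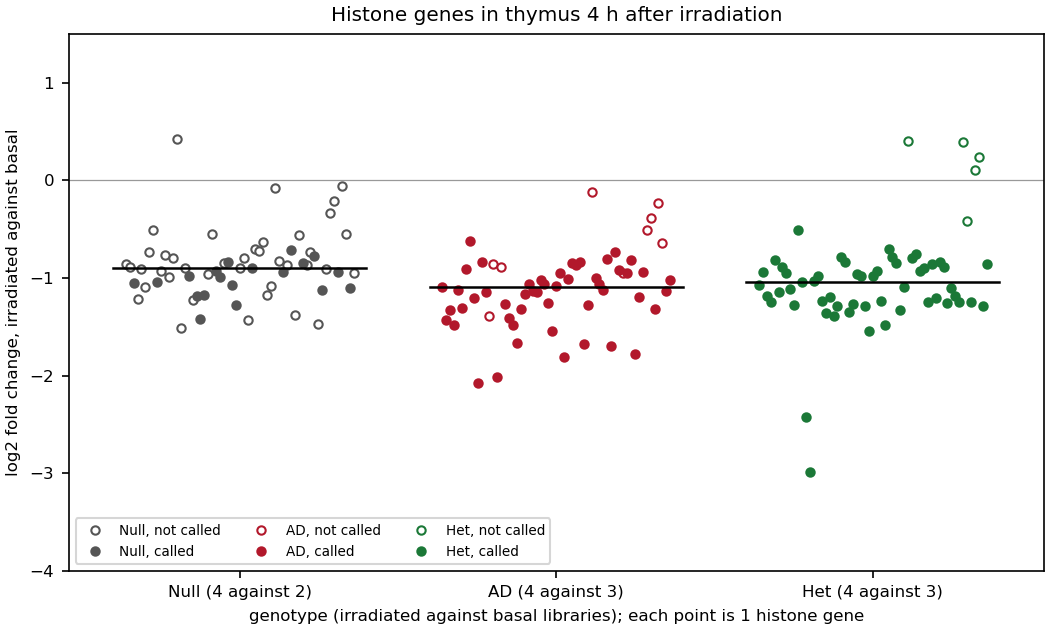
Log2 fold change of 59 histone genes between irradiated and basal thymus in Null, AD and Het mice, with filled points for called genes and a black line at the median. Medians were -0.90, -1.09 and -1.04.

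The response to irradiation was last compared between genotypes. In Het against Null Cdkn1a responded more by 2.84 ± 0.20, Bbc3 by 3.83, Bax by 2.62, Gdf15 by 5.64 and Ccl2 by 4.13, while Bcat1 (-2.26), Dctd (-1.83), the transcription factor gene Myc (-1.23 ± 0.26) and Dkc1 (-1.23) moved further down in Het than in Null. By edgeR this interaction called 811 genes, 559 higher and 252 lower, with adjusted p = 3.07e-10 for Cdkn1a and 0.00704 for Myc. Cycle and repair targets responded more in 19 of 26 with 0 lower (20 and 0 adjusted over the list alone; edgeR adjusted p = 3.67e-12 with an estimated correlation). In AD against Null Cdkn1a responded by 0.01 ± 0.20, and PPAR targets had a median of -0.31, with adjusted p = 2.09e-07 on edgeR values and adjusted p = 0.578 with an estimated correlation, beside adipocyte markers of another cell type at -1.73, adjusted p = 1.53e-16 on edgeR values and adjusted p = 0.437 with an estimated correlation. For AD against Null edgeR called 0 genes, with 972 at unadjusted p under 0.05, and DESeq2 called 2. Without IR Het-631 the Het count was 1329, without basal Null-859 it was 444 (Myc and Dkc1 lost) and without basal Null-923 it was 442 (Dkc1 lost), and without basal AD-702 the AD count was 2.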

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

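The tests of the 3 patterns below were chosen after the results were seen, except the correlation with Adipoq, which was written before its result. The counts of other splits of the same libraries were written down before their results.

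Genes around Trp53 stood apart in irradiated thymus of Null mice against Het, AD and RP, which share the same 4 Null libraries. Against other Null mice, 8 of 15 calls in basal Het thymus, 7 of 15 in basal AD thymus and 2 of 3 in AD intestine lay there. The 2 basal thymus comparisons share their Null libraries. In liver 0 of 42 calls and in pancreas 0 of 8 lay there. Of the tested genes only 300 of 15755 in liver and 295 of 14604 in pancreas lay there. So few calls cannot show that the pattern was absent from these tissues. Of the 7 genes called in AD or RP against Null, 6 lay within 10 Mb of Trp53, among 421 of 22206 tested genes there. Strain variant DNA carried along with the null allele was left open, since the Fisher exact p of 3.09e-10 restates the clustering that prompted it and counts Trp53 itself. Of these 6 genes 0 were called between AD and Het after irradiation, with a largest difference of 0.544. The test cannot decide on an activity of p53 that differs between alleles. Its genes were picked for a call in AD or RP against Null, which leaves out genes where AD resembles Null. Of all 421 tested genes there, 66 were called between AD and Het, beside 3099 of all 22206 tested genes. By a Fisher exact test this share was not shown to differ from that elsewhere (odds ratio 1.15, p = 0.32). Genotyping of strain variants near Trp53 was not analysed here, so the linked DNA itself was not read.

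Clock genes were called between AD and Null in liver, only Nr1d1 and Nr1d2 were called in pancreas, and none was called in intestine, with list adjusted p on edgeR values of 0.102 in liver and 0.21 in intestine with an estimated correlation. The smallest correlation of their differences between 2 tissues was 0.57, which left time of day or feeding at harvest open, since harvest times were not in the labels. A single deviating mouse was argued against for Dbp and Nr1d2 in liver, which kept their calls in 6 of 6 fits with 1 library left out, as did Tef in liver and Nr1d1 and Nr1d2 in pancreas, while Ciart, Arntl and Npas2 lost theirs without AD-700 or AD-701. An effect of the AD allele in every tissue was left open, as the median absolute difference of the clock list in basal thymus was 0.17 of that in liver, with no value from noise alone to set it against. The labels give no group that separates harvest time from genotype.

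Adipocyte markers and PPAR targets had higher medians in AD and Het than in Null basal thymus, with edgeR adjusted p with an estimated correlation of 0.348 and 0.348 in AD and 0.59 and 0.689 in Het, and Het-697 lay near Null (adipocyte mean 3.32 against 3.1 and 2.98). Across PPAR targets, the correlation with Adipoq within irradiated groups ranked with the basal AD difference at a Spearman rho of 0.81, so fat tissue in the dissected thymus may account for it. A lower share of thymocytes as the only cause was argued against, as it would raise the lists of other cell types about alike, and their 6 medians spread over 1.55, from 0 in thymic epithelium and 0.04 in macrophages to the adipocyte list. An effect of the AD allele on PPAR targets was left open, with AD 0.13 above Het in mean log2 CPM (SE 0.25). No imaging or cell sorting of the tissue was analysed here.

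Single libraries stood apart from the other 3 of their group in 16 values of 140 tested. The rule set the gap to the nearest library against the range of the group, so small differences could be marked. Chance alone would mark about 1 in 20 of independent normal values. Some of the 140 values are related, as Adipoq and the adipocyte list are, so an excess over chance was not tested. In irradiated Null-604 Mdm2 stood at 7.1 log2 CPM (others 7.16), the DREAM list at 6.96 (6.69 to 6.73), early double-negative thymocyte markers at 4.05 (3.68 to 3.74) and CD8 lineage markers at 4.15 (3.79 to 3.81). In irradiated Het-631 Xist stood at 7.04 (9.92 to 10.16), Alb at 0.81 (-0.14 to -0.08) and NF-kB targets at 3.56 (4.18 to 4.3), and in Het-595 double-negative markers stood at 3.78 (3.87 to 3.88). In irradiated AD-727 Adipoq stood at 5.08 (4 to 4.13), adipocyte markers at 4.65 (3.7 to 3.85) and hepatocyte markers at 3.65 (-0.06 to 0.54), and in AD-630 Bbc3 stood at 1.85 (2.74 to 2.84). In irradiated RP-649 Cdkn1a stood at 1.93 (2.1 to 2.12), in RP-653 double-positive markers at 8.5 (8.68 to 8.71) and CD8 lineage markers at 4.09 (3.74 to 3.79), and in RP-656 macrophage markers at 4.23 (4.05 to 4.07).

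The effect differed between groups by a test of the difference itself in 2 results. The response to irradiation differed between Het and Null in 811 genes, and the AD difference varied over 4 basal tissues in 42 genes.

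Other splits of the same libraries were counted, each comparison fitted with only its 2 groups, apart from the tissue interaction. Real counts here can thus differ from the full fits, where AD against RP had 0 calls. The numbers of splits that reached the real count include the real split itself. Where that number is 1, no other split reached it. Splits that mix groups with a real difference can have a wider spread within groups, so their counts can lie below those of chance. Of 35 splits, 1 called as many genes as the real one for Het against Null (2208, highest other 2), AD against Het (2365, highest other 7), AD against RP (47, highest other 17), irradiated against basal Het (2370, highest other 214) and irradiated against basal AD (361, highest other 311). For AD against Null 2 of 35 splits reached the real 6 (highest other 6) and for RP against Null 2 reached the real 6 (highest other 12). With 10 splits there are too few for a share under 0.05. There the real and highest other counts were 42 and 6 in liver, 8 and 4 in pancreas, 3 and 4 in intestine, 1 and 59 for basal AD against Het, 42 and 9 for the tissue interaction and 1 and 0 for the overlap of tissues. The splits that reached the real count there were 1, 1, 2, 6, 1 and 1.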

How the results depend on the processing

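The alternatives were planned before the files were read, except the Adipoq covariate, and the cause of a moved value was not tested unless stated. RLE scaling gave 6 calls in intestine and kept 316 of 316 named genes. Without the filter the calls were 15 (irradiated AD against Null), 50 (intestine), 454 (liver), 209 (pancreas), 403 (basal AD against Null), 353 (basal Het against Null) and 16 (basal AD against Het), and 297 named genes kept their side of the threshold. With an Xist covariate they were 10 (irradiated AD against Null), 95 (liver), 62 (pancreas), 38 (basal AD against Null) and 2 (basal AD against Het). DESeq2 called 81 (irradiated AD against Null), 30 (RP against Null), 14 (AD against RP), 102 (intestine), 201 (liver), 52 (pancreas), 168 (basal AD against Null), 107 (basal Het against Null), 12 (basal AD against Het), 404 (tissue interaction), 321 and 120 (irradiated against basal AD and Null), 1220 and 2 (responses of Het and AD against Null). With only the 2 groups in the fit the counts were 2208 (irradiated Het against Null), 47 (AD against RP), 167, 23 and 1 (basal AD against Null, Het against Null and AD against Het), and 361, 2370 and 3 (irradiated against basal AD, Het and Null), with fewer libraries to estimate the spread.

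With the Adipoq covariate, chosen after seeing the data, basal thymus gave 25 calls for Het against Null, 5 for AD against Null and 1 for AD against Het. Under it PPAR targets, fatty acid oxidation, lipid synthesis and adipocyte markers reversed to -0.33, -0.32, -0.69 and -0.44 in Het against Null. In AD against Null they reversed to -0.47, -0.41, -1.08 and -0.74, with fibroblast markers at -0.12. As Adipoq is itself a fat cell gene, the covariate can take out the difference of these lists whatever its cause. Trp53, Ybx2 and Nlrp1c-ps also lost their calls in AD against Null under it, so these reversals do not tell causes apart. In AD against Het PPAR targets, fatty acid oxidation and adipocyte markers reversed to -0.1, -0.09 and -0.21, and without Het-697 to -0.09, -0.07 and -0.12 (at most 0.21, 0.19 and 0.55 without another library). Without AD-727 hepatocyte markers reversed to -0.19 in irradiated AD against Null (at most 2.24 without another library) and PPAR targets to -0.02 in AD against RP (at most 0.19). Acinar markers in liver reversed to -1.04 without AD-702 (at most 5.07). No named gene that was called in the main fit reversed. Named genes without a call changed sign in 54 values with 1 library left out, 4 under the Adipoq covariate and 1 under the Xist covariate.

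With an estimated correlation 19 of 843 list tests passed in place of 238. The shared covariance of Het and AD was 0.0152 with the Null libraries split. The overlap of tissues was 11 genes with DESeq2 and 56 at unadjusted p under 0.01. The replicate block for mouse gave 48 genes in the tissue interaction against 42, and this pairing could be fitted only there. In the other comparisons no paired analysis was possible because the groups compared share no mouse.

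Leaving out 1 library at a time, the counts ran from 3340 to 5213 (irradiated Het against Null), 4 to 27 (AD against Null), 4 to 8 (RP against Null), 0 to 4 (AD against RP), 2189 to 4665 (AD against Het), 8 to 234, 7 to 29 and 0 to 8 (basal Het against Null, AD against Null and AD against Het), 3 to 8 (intestine), 3 to 87 (liver), 4 to 26 (pancreas), 7 to 75 (tissue interaction), 0 to 60, 2728 to 4108 and 67 to 116 (irradiated against basal Null, Het and AD), and 442 to 1329 and 0 to 2 (responses of Het and AD). Where it left 1 Null library in basal thymus, that library was assumed to vary like the other groups. Changes of 2-fold were often missed at the depth, group size and spread of these libraries, whose parts were not separated: in simulated data edgeR recovered 39.4% of 2-fold changes in liver, 46% in intestine, 56.9% in pancreas and 61.2% in irradiated AD against Null thymus.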

Other observations

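The sex genes Xist and Ddx3y varied within mice as well as between them. In mouse Null-923, Xist had 2592 counts in thymus and 7 in liver, and in AD-700 and AD-701 it had 1494 and 1592 in thymus and 11 and 3 in liver. Xist and Ddx3y were high together in irradiated Het-595, at 10.16 and 7.63 log2 CPM, in Het-631 at 7.04 and 7.23, and in basal Het-855 at 7.34 and 7.58. In irradiated Null-593, by contrast, Xist stood at 10.15 and Ddx3y at -0.95. Other thymus libraries with high Xist had low Ddx3y above that level, with 11.1 CPM in Null-604, 9.92 in RP-649 and 5.94 in Het-594 against 0.453 in Null-593. Mixing of thymus samples or libraries was not tested, and it is an open question for the thymus values printed here and for Xist as a measure of sex.

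Of 18 clock genes, 11 had the same sign in intestine, liver and pancreas. Their AD differences correlated at 0.84 between intestine and liver, at 0.77 between intestine and pancreas and at 0.57 between liver and pancreas, and no value without an effect was computed for tissues of the same mice.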
